A study of Mus musculus with 8 samples.

How the data were processed

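Chromatin-associated RNA from 8 samples of primary mouse embryonic fibroblasts was depleted of ribosomal RNA, made into stranded libraries and sequenced as single-end reads, per the labels' protocols. Tools named in the submitters' processing notes are cutadapt 1.12, STAR, featureCounts 1.5.0 and DESeq2, with the genome build mm10. The deposited values are whole-number counts per gene for each library, with gene coordinates and exon lengths beside them, per the file headers. The deposited length of a gene equalled its merged exon length in 100.0% of 2000 rows checked, so the counts are taken as exonic. The strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Overlapping and antisense genes, and members of families with near-identical copies such as the H2 genes, are therefore uncertain.

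The table held 45706 gene rows, of which 98.77% were given a symbol by their identifier. Samples were grouped by the genotype and time in the labels. No pair of libraries was a duplicate, since the chi-square per degree of freedom between pairs of libraries ran from 8.43 to 56.5. Library totals ran from 12359817 to 15607331 counts. The limit that a count of 0 allows, 3 counts, corresponds to 0.192 to 0.243 CPM of the total. Intervals and floors cover counting error only, since reads amplified by PCR are not independent molecules. Nothing says that the libraries came from separate cultures or animals.

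Genes with at least 10 counts in at least 2 libraries were kept, which left 15049. Counts were scaled by TMM (factors 0.817 to 1.21) and tested with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The late response was the mean of 45 and 60 min against 0 min, within each genotype and as the difference between genotypes, from a fit of 6 cell means with 2 residual degrees of freedom. The genotype comparison used all 8 libraries with time as a block and 3 residual degrees of freedom. Standard errors were the log2 fold change divided by the square root of F. CPM values are counts scaled to the TMM-adjusted library size, computed here. Ratios of a library to 0 min carry exact Clopper-Pearson intervals at 95%.

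Gene lists and cell type markers, 28 in all, were fixed before the data were examined, and the 27 with at least 2 measured members were tested with camera (preset correlation 0.01, and estimated) and fry in limma 3.58.1. The erythroid markers were too low to test, with a summed level of at most 0.216 CPM in any library. Named genes are, for each contrast, the 10 highest and 10 lowest called genes with a mean of at least 20 counts and the same sign in both late libraries (at all 4 times for genotype), without predicted gene models, a fixed set of TNF and immediate early genes, and the 4 members of each list with the smallest p. For single times they are the 10 largest ratios with at least 50 counts. Values of 1 gene are not reported here.

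The fits were tested on simulated counts for the 15049 genes in which 66 or 67 genes each were changed 1.5-fold, 2-fold and 4-fold. For the late WT response, 97.0% of genes changed 4-fold and 41.8% of those changed 2-fold were recovered. For the late KO response the shares were 75.8% and 47.8%, and for the difference between responses 74.2% and 8.96%. For the genotype comparison they were 97.0% and 85.1%. Each share rests on 66 or 67 genes, and the late WT and KO contrasts have the same form. The gap between their shares is therefore not taken as an effect of genotype. Simulated counts cannot tell whether the real late libraries, which are different times, vary like replicates. The shares thus do not show how many real changes were recovered. Alternatives fixed before the data were examined were DESeq2 1.42.0, RLE scaling, total counts, other filters, a 2-fold threshold, robust empirical Bayes, limma-voom, other groupings of the times, no time block, subsets of times, and leaving out each library. Figures were drawn with matplotlib 3.10.9.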

Results

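Chromatin-associated RNA, the fraction that holds transcripts still attached to or close to their genes, was sequenced from primary mouse embryonic fibroblasts of the C57BL/6 strain. Wild-type (WT) cells were compared with cells that lack both RelA and cRel, subunits of the transcription factor NF-kB that activate transcription (the knockout, KO). Cells were starved of serum overnight and given tumour necrosis factor (TNF) at 10 ng/ml, a cytokine that activates NF-kB. Libraries were taken at 0, 15, 45 and 60 min, 1 per genotype and time, so the 8 libraries hold no replicates. They include no untreated library at 15, 45 or 60 min. Changes after TNF therefore cannot be told apart from those of time, handling or longer starvation. The series title puts the question as how RelA controls its target genes in the inflammatory response. The libraries held 12359817 to 15607331 counts. Between 56.05% and 68.97% of these fell on 3 gene models, of which Gm26917 and Gm42418 neighbour each other on chromosome 17 in a segment known to carry ribosomal RNA sequence. The other genes shared 4213829 to 6076931 counts per library.

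The targeted genes were examined first. Rela (chromosome 19, 5637483 to 5648130, mm10) had 324, 406, 704 and 589 exonic counts in WT at 0, 15, 45 and 60 min, and 306, 241, 291 and 324 in KO. Rel (chromosome 11, 23736847 to 23770970) had 151, 173, 805 and 506 counts in WT, and 478, 308, 538 and 633 in KO. Both loci thus gave reads from exons in the KO libraries. The part removed from each allele is not given in the sources used here, so counts over the whole gene check nothing about the labels.

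In WT cells, the mean of the 45 and 60 min libraries was compared with 0 min to find the genes that changed late after TNF. Transcripts of 628 genes rose and 197 fell, of 15049 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Among named genes with a mean of at least 20 counts, the largest rises included those of chemokines, which attract leukocytes. Cxcl2 rose by a log2 fold change of 6.61 ± 0.52, adjusted p = 1.63e-05, Ccl20 by 6.21 ± 0.64, adjusted p = 0.000132 and Cxcl10 by 5.96 ± 0.32, adjusted p = 1.49e-06. Each of these started from few counts: Cxcl2 went from 3 at 0 min to 347 at 45 min. Tnfaip3 (chromosome 10, 19000910 to 19015657), which encodes the NF-kB inhibitor A20, rose by 5.39 ± 0.35, adjusted p = 2.70e-06. Sele, an endothelial adhesion molecule, rose by 5.89 ± 0.97, and the interferon-inducible GTPase gene Gbp5 by 5.17 ± 0.60. The genes with the lowest fold changes included the transcription factor genes Osr2 (-2.63 ± 0.35, adjusted p = 0.000809) and Osr1 (-1.74 ± 0.20), the membrane peptidase gene Mme (-1.83 ± 0.25) and Rgs2, a regulator of G protein signalling (-1.72 ± 0.29). Calls were lost in 3 of 19 alternatives for Cxcl2, 3 of 18 for Sele and 1 of 19 for Rgs2. With the WT baseline from 15 min, an alternative chosen after the data were seen, these were at 0.46, 1.15 and -0.997, all short of the threshold.

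Called members were counted in WT for lists fixed before the data were examined. All 5 NF-kB subunit genes rose, from Rela (1.11 ± 0.19) to Relb (2.81 ± 0.20), with Nfkb1 at 2.29 ± 0.19 and Nfkb2 at 2.71 ± 0.19. Of 16 feedback regulators of NF-kB, 12 rose (13 adjusted over the list alone), among them Nfkbia and Nfkbie, which encode inhibitors that hold NF-kB in the cytoplasm (3.94 ± 0.25 and 4.50 ± 0.24), and Tnfaip2 (3.92 ± 0.25). Of 14 chemokines, 9 rose and 1 fell (11 and 1 adjusted over the list alone). Ccl2 rose by 4.44 ± 0.28 and Ccl7 by 3.08 ± 0.24. Of 17 cytokines and growth factors 5 rose (8 adjusted over the list alone), led by Csf1, the macrophage growth factor (3.48 ± 0.20), and Lif (3.14 ± 0.26). With the WT baseline from 15 min, 3 of these 17 were higher and 1 lower, and 8 feedback regulators and 6 chemokines were higher. Il6 was at 2.64 ± 0.91 with an adjusted p of 0.127 and at most 22 counts. Among 14 genes of adhesion and matrix proteolysis 7 rose (10 adjusted over the list alone), including the leukocyte adhesion genes Icam1 (4.26 ± 0.24) and Vcam1 (3.02 ± 0.25). Among 12 survival genes 6 rose (9 adjusted over the list alone), including Birc3 (2.80 ± 0.23) and Gadd45b (3.07 ± 0.29). Of 18 genes of innate sensing and TNF receptors 10 rose and 1 fell (11 and 1 adjusted over the list alone). Ripk2, a kinase in bacterial sensing, rose by 4.38 ± 0.25 and Fas by 2.29 ± 0.25. Of 15 antigen presentation genes 6 rose (7 adjusted over the list alone), such as the class I heavy chain gene H2-K1 (2.10 ± 0.23), whose counts are uncertain because near-identical copies exist. Of 32 immediate early genes, which respond to many stimuli without new protein synthesis, 9 rose and 1 fell (13 and 4 adjusted over the list alone), with Klf10 at 3.88 ± 0.27 and Junb at 1.70 ± 0.31. With the WT baseline from 15 min 1 was higher and 9 lower, and Junb was at -0.20. The call of Junb was lost in 5 of 19 alternatives. In the interferon response list of 28 genes, 3 rose and 1 fell (5 and 5 adjusted over the list alone). Irf1 rose by 4.11 ± 0.24 and Ifit3 fell, at -1.32 ± 0.29. Of 20 genes of cholesterol synthesis 9 rose (14 adjusted over the list alone), among them Msmo1 (1.33 ± 0.18), and 2 rose with the WT baseline from 15 min. The calls of Nfkbia, Rela and Ccl7 were lost in 3 of 19, 2 of 19 and 1 of 19 alternatives, and with that baseline they were at 0.59, 0.67 and 0.66, short of the threshold. The call of Ifit3 was lost in 6 of 19 alternatives, 1 of them without the WT 45 min library (-1.15).

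The genes that fell in the chemokine, innate sensing and immediate early lists were Cxcl12, Tlr4 and Fos, named after their values were seen.

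As sets, 11 of 27 lists stood apart from other genes in the WT response when camera used a preset correlation of 0.01. None did with an estimated correlation, where the adjusted p was 0.0678 for the feedback regulators, 0.0678 for the chemokines and 0.240 for cholesterol synthesis. The fry test, which compares a list with no change and not with other genes, called 5 lists. The counts of 628 and 197 became 379 and 47 with DESeq2, 248 and 30 with no filter on low counts, and 304 and 280 with total counts in place of TMM scaling, where the share of calls that were higher went from 76.1% to 52.1%. The 45 and 60 min libraries stand in for replicates although they are different times, and the lone 0 min library was assumed to vary like the others.

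**Figure D1:**
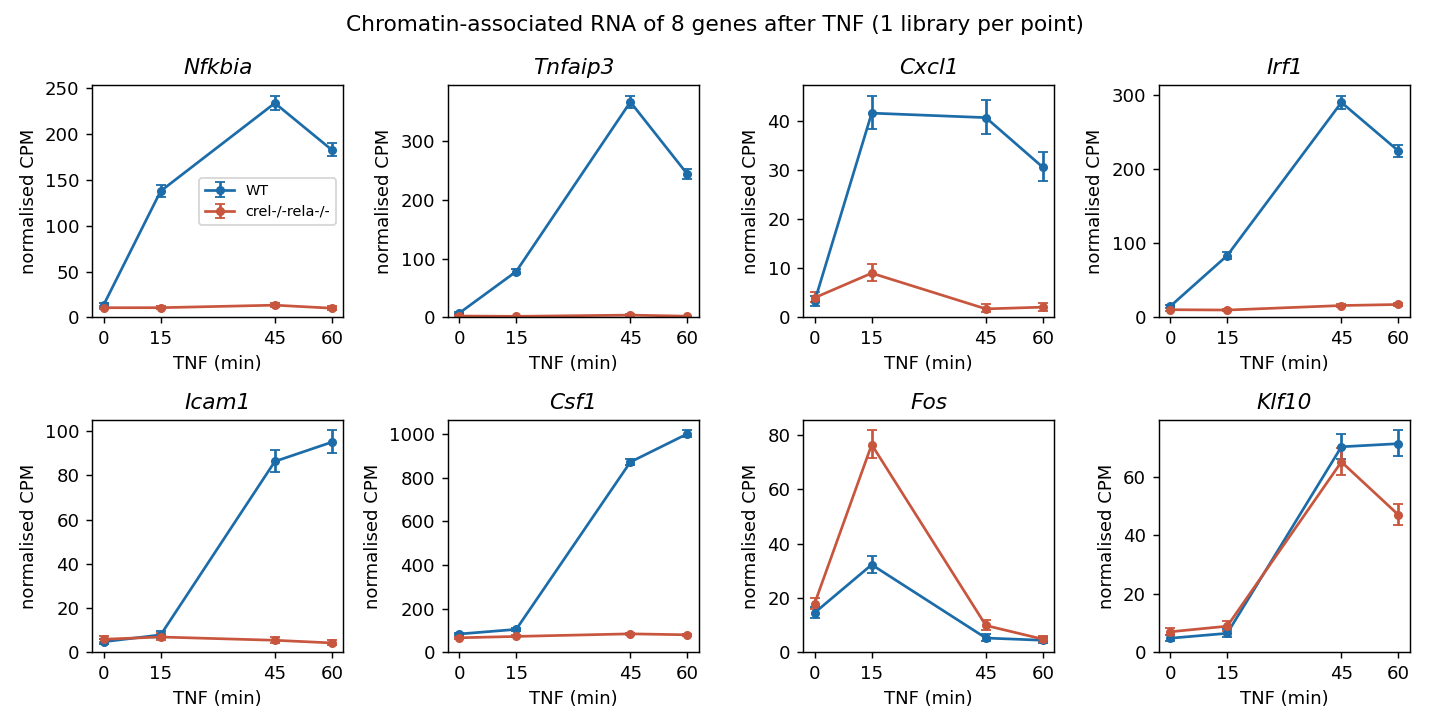
Normalised CPM (counts scaled to library size) of 8 genes against minutes of TNF in WT (blue) and crel-/-rela-/- cells (red), 1 library per point, with exact 95% Poisson intervals that cover counting error alone. Nfkbia, Tnfaip3, Cxcl1 and Irf1 were already high at 15 min in WT, Icam1 and Csf1 were high only at 45 and 60 min, and Fos and Klf10 moved in both genotypes.

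The 15 min libraries show which transcripts came first. The single times were described by size, and no test was run on them. Genes were counted where the ratio to 0 min was at least 2-fold, its exact interval excluded 1, and the higher library held at least 20 counts. By this rule 124 genes were higher and 173 lower at 15 min in WT, 615 and 417 at 45 min, and 747 and 491 at 60 min. The ratios compare libraries, not conditions. In WT at 15 min the leading genes were Cxcl2, with a log2 ratio of 6.21 (95% interval 4.64 to 8.50), Cxcl1 at 3.67 (95% interval 3.25 to 4.12), Tnfaip3 at 3.43 (95% interval 3.14 to 3.72) and Nfkbia at 3.34 (95% interval 3.13 to 3.56). Nfkbia (chromosome 12, 55489411 to 55492647) had 204 counts at 0 min and 1916 at 15 min. Other responders were nearer to their starting level at 15 min and high later. Icam1 had 71, 109, 1204 and 1314 counts across the 4 times, and Nfkb1 had 1043, 1066, 4811 and 4615. The immediate early genes Fos, Jun and Atf3 were above their 0 min level at 15 min in both genotypes. Fos had a log2 ratio of 1.15 (95% interval 0.91 to 1.39) in WT and 2.09 (95% interval 1.90 to 2.29) in KO, and Jun had 0.83 (95% interval 0.71 to 0.96) and 2.02 (95% interval 1.92 to 2.13). Atf3 was at 1.30 (95% interval 0.82 to 1.80) in WT and 1.70 (95% interval 1.27 to 2.15) in KO. In KO, 87 genes were higher and 166 lower at 15 min, 388 and 396 at 45 min, and 450 and 476 at 60 min. Nfkbia in KO was at 0.00 (95% interval -0.34 to 0.35) at 15 min. With total counts in place of TMM scaling, the 15 min counts were 46 higher and 691 lower in WT, and 33 and 499 in KO.

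In KO cells, the same late contrast asked which transcripts changed after TNF without RelA and cRel. It called 198 genes higher and 78 lower (edgeR, adjusted p under 0.05). Klf10 (chromosome 15, 38294413 to 38300707), a transcription factor gene induced by many growth factors, rose (adjusted p = 0.000278), with 117, 101, 820 and 626 counts at the 4 times. Hbegf, an EGF receptor ligand, rose by 2.33 ± 0.23, adjusted p = 0.000541. Other named genes that rose were Lfng, a modifier of Notch receptors (2.75 ± 0.35), the kinase gene Nuak2 (2.30 ± 0.21), the clock-linked repressor gene Bhlhe41 (2.07 ± 0.22) and Gadd45b (1.99 ± 0.27). Of the 198 genes, 197 also had a log2 fold change above 0 in WT, with medians of 1.22 in KO and 1.02 in WT, and 113 were called in WT as well, against 8.26 for independent lists. Of the NF-kB lists, 1 of 5 subunit genes rose (Nfkb2, 0.78 ± 0.18, adjusted p = 0.0477), none of 16 feedback regulators did (3 higher and 1 lower adjusted over the list alone), and of 14 chemokines none rose and 1 fell (Cxcl5, -1.43 ± 0.32, and 1 higher and 2 lower adjusted over the list alone). Of 32 immediate early genes 3 rose and 2 fell (9 and 3 adjusted over the list alone), Dusp4 among the former (1.42 ± 0.24). With the KO baseline from 15 min, 1 of these was higher and 12 lower. Nfkbia stood at 0.14 ± 0.24, Tnfaip3 at 0.30 ± 0.42 and Icam1 at -0.29 ± 0.24, all short of the threshold. The call of Nfkb2 was lost in 10 of 19 alternatives, among them without the WT 0 min, KO 45 min or KO 60 min library (0.77, 0.80 and 0.76), and that of Cxcl5 in 6 of 19, among them without the KO 45 min or KO 60 min library (-1.19 and -1.75). Of 20 cholesterol synthesis genes 7 rose (19 adjusted over the list alone), for example Lss (1.20 ± 0.18) and Fdps (1.31 ± 0.20). This list stood apart with the preset correlation (adjusted p = 2.28e-20, camera) and not when it was estimated (adjusted p = 0.320 with an estimated correlation). With the KO baseline from 15 min, 2 cholesterol synthesis genes rose. Calls were also lost in 3 of 19 alternatives each for Dusp4 and Fdps, 2 of 19 for Lss and 1 of 19 each for Lfng and Gadd45b.

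The lowest fold changes in KO were those of 3 cartilage genes. Col2a1 (chromosome 15, 97975602 to 98004695), the main cartilage collagen gene, was at -4.02 ± 0.39, adjusted p = 0.000541, Col9a1 at -4.46 ± 0.44 and Acan at -3.71 ± 0.37. Of 6 cartilage and bone markers 4 fell (also 4 adjusted over the list alone), and the list had an adjusted p = 0.320 with an estimated correlation. Nearly all of this lay in the 0 min library, where Col2a1 had 5219 counts against 91, 114 and 389 later. Tg, the thyroglobulin gene, had 331 counts there and 17 at 15 min. Epithelial markers summed to 17.7 CPM in that library and to 3.53 to 4.61 CPM in the later KO libraries. With the 15 min library as the KO baseline, an alternative chosen after the data were seen, 72 genes were higher, of which 63 were among the 198, and Col2a1, Col9a1 and Acan were above 0 and not called. In all, their calls were lost in 3 of 19, 1 of 16 and 2 of 18 alternatives, with Acan at -2.79 with 0 and 15 min together as baseline. Without the WT 45 min library, which shares the estimate of spread, the KO counts were 398 higher and 231 lower, without the WT 60 min library 459 and 317, and without the KO 60 min library 33 were lower. DESeq2 called 16 genes lower, and with no filter 8 were higher and 9 lower. With total counts 57 were higher and 156 lower, a share of higher calls of 26.8% in place of 71.7%.

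The difference between these responses tests directly which log2 responses, taken with their sign, were larger in WT. The log2 response was larger in WT for 74 genes and larger in KO for 1 (edgeR, adjusted p under 0.05). Of the 74, 68 were also called higher in WT, with a median log2 fold change of 2.46 in WT and -0.13 in KO. They were chosen for a larger response in WT, which favours a low KO median. Adjusted over the 628 genes called higher in WT alone, the response was larger in WT for 310 and smaller for 3. The 628 were chosen for their rise in the same WT libraries, which favours a larger WT response. Of all 628, 491 had a KO log2 fold change above 0 and 113 were called higher in KO. The WT and KO lists compare different libraries but share the scaling and the estimate of spread. The 74 and the 628 share the WT libraries, so their overlap is not independent. Inhibitors and regulators of NF-kB were among the 74. The difference was 5.09 ± 0.55, adjusted p = 0.000693 for Tnfaip3, 4.58 ± 0.43, adjusted p = 0.000187 for Nfkbie and 3.79 ± 0.33, adjusted p = 0.000149 for Nfkbia. Of 16 feedback regulators 10 differed (12 adjusted over the list alone), Bcl3 among them (4.09 ± 0.44). Of 5 subunit genes 3 differed (5 adjusted over the list alone), namely Relb (2.76 ± 0.27), Nfkb1 (1.99 ± 0.25) and Nfkb2 (1.93 ± 0.24). Of 14 chemokines 5 differed (8 larger in WT and 1 in KO adjusted over the list alone), including Cxcl10 (5.44 ± 1.06, adjusted p = 0.0473), Cxcl1 (4.49 ± 0.42) and Ccl2 (3.74 ± 0.51). Other large differences were in Ripk2 (5.06 ± 0.34), Icam1 (4.55 ± 0.33), Traf1 (4.63 ± 0.91), Casp4, an inflammatory caspase gene (4.75 ± 0.72), and Csf1 (3.17 ± 0.25). Calls were lost in 9 of 18 alternatives for Traf1, 4 of 18 for Cxcl10, 3 of 18 for Tnfaip3, 3 of 18 for Ccl2, 2 of 18 for Nfkbia, 2 of 18 for Cxcl1, 2 of 18 for Casp4 and 1 of 18 each for Bcl3, Nfkb1 and Nfkb2. With 0 and 15 min together as baseline Tnfaip3 was at 2.39 and Nfkbia at 1.32, both short of the threshold. Leaving out the KO 45 min library ended the calls of Traf1 (4.52) and Cxcl10 (5.08), and leaving out the KO 60 min library that of Traf1 (4.76). Members of other lists that differed were 2 of 14 for adhesion and matrix proteolysis, 3 of 12 survival genes, 3 of 18 for innate sensing, 2 of 17 cytokines, 2 of 15 for antigen presentation, 1 of 28 for interferon and 1 of 32 immediate early genes. Adjusted over the list alone these were 10, 5, 8 larger in WT and 1 in KO, 2, 5, 2 and 3. No leukocyte marker of 14 was called different in response. As sets, 11 of 27 lists stood apart by camera and none with an estimated correlation, where the feedback regulators had an adjusted p of 0.0871. The fry test against no change called 2.

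Cxcl2 and Ccl20 had no count in the KO 0 min library, so their KO response cannot be measured. At 45 and 60 min together Cxcl2 had 567 counts in WT and 2 in KO, a ratio of 264-fold (95% interval 72.8 to 2187, counting error alone), and Ccl20 had 429 and 1. No cholesterol synthesis gene of 20 was called different in response. In simulated counts this test recovered 8.96% of genes changed 2-fold, so the lack of calls does not show equal responses. Fos (-0.29 ± 0.44) and Egr1 (-0.12 ± 0.48) were also short of the threshold. The 6 genes of the 74 that were not called higher in WT were Tg, Bcam, Col15a1, Fgfr3, Pth1r and Cxcl5, named after their values were seen, and all 6 were called lower in KO. The gene with a larger KO response was the gene model Gm25848. With the KO baseline from 15 min and the WT baseline still at 0 min, 53 of the 74 genes kept the call. A rise in KO by 15 min is then taken off the KO response alone, which favours a larger difference. Of the lists, 9 of 16 feedback regulators and 5 of 14 chemokines differed. In the same fit the adhesion and matrix proteolysis genes that differed went from 2 to 5 of 14, the immediate early genes from 1 to 4 of 32, the survival genes from 3 to 2 of 12 and the p53 targets from 0 to 1 of 20. The 74 became 14 with no filter and 179 with 0 and 15 min together as baseline. Without the WT 45 min library there were 153 genes larger in WT and 7 in KO, without the WT 60 min library 147 and 12, and without the KO 45 min library none was larger in KO.

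**Figure D2:**
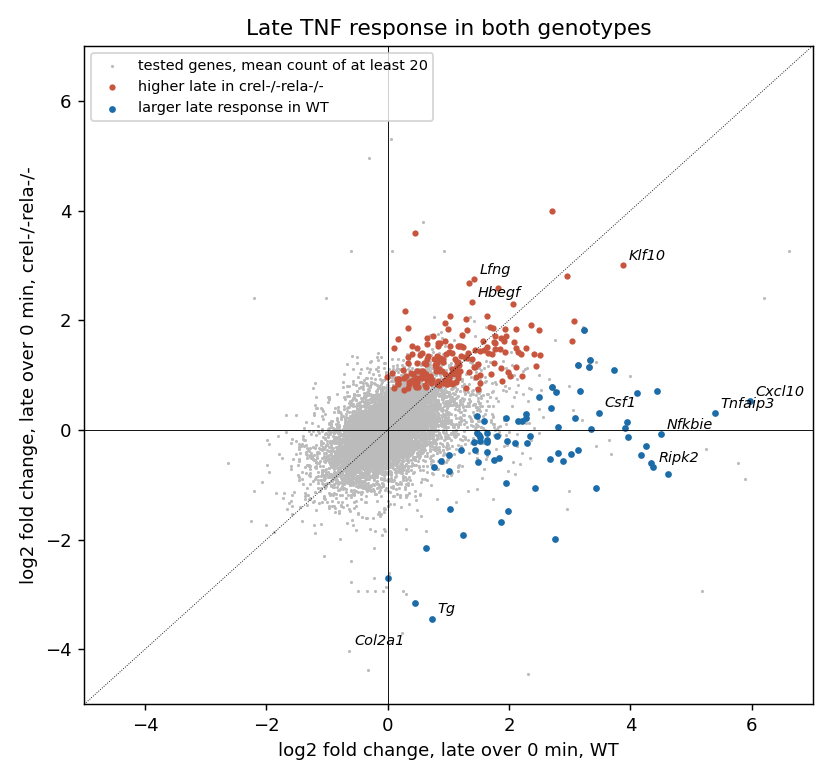
Log2 fold change of the mean of 45 and 60 min over 0 min in WT (x axis) against crel-/-rela-/- cells (y axis), for tested genes with a mean count of at least 20. Blue points are genes with a larger response in WT. The 68 of them called higher in WT lie to both sides of 0 on the y axis, with medians of 2.46 on the x axis and -0.13 on the y axis. The other 6 lie below 0 on the y axis, from Cxcl5 (-1.43) to Tg (-3.44). Red points are the genes called higher in KO, 197 of 198 of which lie above 0 in WT.

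Across all 4 times, KO libraries were compared with WT libraries with time as a block, to find the genes whose level differed. The error of this test is how the genotype difference varied between times, with 1 library per genotype and time. Its p-values do not measure variation between embryos or cell preparations, which cannot be told apart from genotype. Levels of 1025 genes were higher and 1421 lower in KO (edgeR, adjusted p under 0.05). Interferon response genes were lower in KO in 27 of 28 cases (also 27 adjusted over the list alone), with Oasl2 at -1.89 ± 0.13, adjusted p = 1.83e-05, Oas2 at -2.88 ± 0.23 and Ifih1, an RNA sensor gene, at -1.54 ± 0.13. Antigen presentation genes were lower in 14 of 15 cases (15 adjusted over the list alone), with H2-D1 at -3.02 ± 0.26 and B2m, the light chain of class I molecules, at -1.58 ± 0.15. Both lists differed with the preset correlation (adjusted p = 2.61e-37 and 1.75e-15, camera). With an estimated correlation the adjusted p was 0.159 for the interferon list and 0.231 for antigen presentation. The summed interferon list had 486 CPM in WT and 222 in KO already at 0 min. Chemokines were lower in 11 and higher in 1 of 14 cases, and feedback regulators lower in 13 of 16 (12 and 14 lower adjusted over the list alone), with Cxcl16 at -4.25 ± 0.30. At 0 min, before TNF, the summed chemokines had 127.8 CPM in WT and 127.7 in KO. The feedback regulators had 219.6 and 198.0. Abundant members weigh most in these sums. Leukocyte markers were lower in KO as well. Of 14, 13 were lower in KO (also 13 adjusted over the list alone, adjusted p = 0.0787 with an estimated correlation), with Ptprc at -7.12 ± 0.30 and Csf1r at -4.85 ± 0.23. Their summed level was 108, 95.5, 93.8 and 77.4 CPM in WT and 9.39, 9.45, 7.23 and 8.56 in KO. Nlrp3 and Cybb, genes of the inflammasome and of the phagocyte oxidase, had no count in any KO library. Against a floor of 3 counts over the group they were at least 88.5-fold and at least 78.0-fold lower in KO.

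Members of other lists were higher in KO. Of 20 cholesterol synthesis genes 16 were higher (18 adjusted over the list alone), with Msmo1 at 0.77 ± 0.08 and Fdps at 0.90 ± 0.11. Of 32 immediate early genes 14 were higher (18 higher and 1 lower adjusted over the list alone), with Fos at 0.71 ± 0.17, Jun at 0.61 ± 0.16 and Ccn2 at 1.01 ± 0.10. Both lists stood apart with the preset correlation (adjusted p = 1.39e-12 and 7.78e-06, camera) and neither did with an estimated one (adjusted p = 0.159 and 0.382). The fry test, which asks whether a list moved in 1 direction and not whether it stood apart from other genes, gave an adjusted p of 0.0126 and 0.114. The calls of Fos and Jun were lost in 6 of 20 and 8 of 20 alternatives, among them each of those without a 15 or 45 min library, where Fos was at 0.45 to 0.66 and Jun at 0.40 to 0.53. Those of Msmo1 and Fdps were lost in 2 of 20 and 2 of 20, and those of Ccn2, Hbegf and Col2a1 in 1 of 20 each. Hbegf was at 1.43 ± 0.16. Of 6 cartilage and bone markers 5 were higher, with Col2a1 at 5.43 ± 0.60, and outside this list Rarb, a retinoic acid receptor gene (2.94 ± 0.24), and Des, the muscle filament gene desmin (2.47 ± 0.24), were higher at every time. Without the KO 0 min library the counts were 13 of 20 for cholesterol synthesis, 24 of 28 lower for the interferon list and 4 of 5 measured cartilage markers. Positional Hox genes, which record where along the embryo a fibroblast came from, were higher in 4 and lower in 12 of 33 cases, with Hoxd4 at -1.52 ± 0.13. Embryo sex differed as well. Xist, transcribed from the inactive X chromosome of female cells, had 19258 counts in WT and 16 in KO at 0 min. The Y-linked gene Uty had 364 and 966 counts, so the WT libraries held transcripts of both kinds. Without the WT 45 min library the counts of 1025 and 1421 were 433 and 734, without the KO 45 min library 410 and 744, and without the WT or KO 15 min library 648 or 644 were higher. With total counts they were 477 and 2902, and the share of calls that were higher went from 41.9% to 14.1%.

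**Figure D3:**
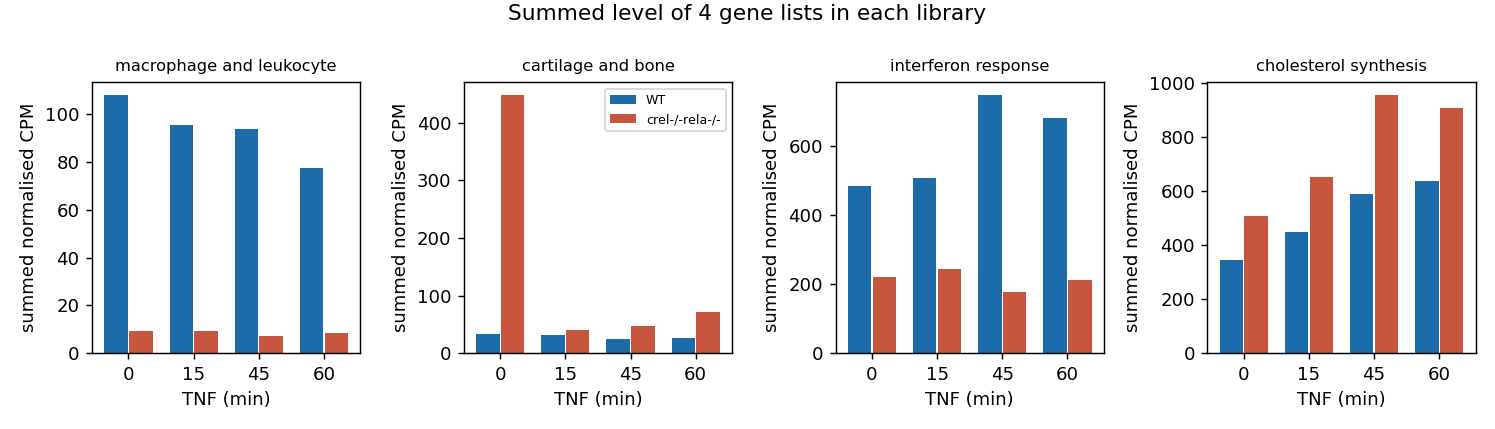
Summed normalised CPM of 4 gene lists in each library against minutes of TNF, in WT (blue bars) and crel-/-rela-/- cells (red bars). Leukocyte markers stayed between 77.4 and 108 CPM in WT and at most at 9.45 CPM in KO, and cartilage markers reached 448 CPM in the KO 0 min library against at most 70.8 CPM in the others.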

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

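The tests with the KO 15 min baseline, with the leukocyte and cartilage markers, of genes 2-fold apart under both scalings, of genes near the targeted alleles, and of splits within times were chosen after the results they bear on had been seen. What drew attention was a response that differed between the genotypes. The late log2 response was larger in WT for 74 genes and larger in KO for 1, by the edgeR test of the difference itself. Among named genes the log2 response in WT minus that in KO was 5.44 for Cxcl10, 5.42 for Cilp2, 5.09 for Tnfaip3, 5.06 for Ripk2, 4.94 for Stx11, 4.75 for Casp4, 4.63 for Traf1, 4.58 for Nfkbie, 4.55 for Icam1, 4.49 for Cxcl1, 2.76 for Relb, 1.99 for Nfkb1, 1.93 for Nfkb2, 3.79 for Nfkbia, 3.74 for Ccl2, 3.47 for Vcam1, 3.23 for Birc3 and 3.43 for Irf1. The calls of Cilp2 and Irf1 were lost in 2 of 18 and 2 of 18 alternatives, with Cilp2 at 2.95 with the KO baseline from 15 min and Irf1 at 1.68 with 0 and 15 min together as baseline.

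The log2 response, taken with its sign, was larger in WT than in KO for the 74 genes. For 6 of them no rise was called in WT and a fall was called in KO. With the KO baseline from 15 min and the WT baseline still at 0 min, 53 of the 74 genes kept the call. This contrast thus left out the KO 0 min library, which still entered the filter, the scaling and the choice of the 74 genes. The baselines differ in time, and a rise in KO by 15 min is taken off the KO response alone. This favours a larger difference, so the count itself cannot exclude an odd KO 0 min library as a cause. The summed feedback regulators had 198, 207, 198 and 209 CPM in KO at 0, 15, 45 and 60 min. In WT they had 220, 504, 1287 and 1110. KO at 0 min was thus near the later KO libraries and WT at 0 min. For this list, where abundant members weigh most, these values argue against that library as the cause. Other genes of the 74 are not covered. Leukocytes present in the WT libraries alone cannot be told apart from fibroblasts as the source. The median rise of the 74 genes was 0.386 of the summed CPM of 14 leukocyte markers in WT, and the rise was above that sum for 10 genes and above the highest marker (Mrc1, at 17.0 CPM) for 54. A gene induced within leukocytes can pass the level of their markers, so these values exclude neither source. A response of the fibroblasts that needs RelA and cRel is the biological explanation the design gives, and it stays open beside the leukocytes.

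The genotypes differed in 2446 genes. The 8 libraries were split into 4 and 4 in 35 ways, without a time block. Only the real split itself gave its 1067 calls, 1 of 35. These splits treat the libraries as exchangeable, although the genotypes share times and nothing says that the libraries are separate cultures. They therefore cannot exclude a chance difference between the cell preparations of the 2 genotypes. The highest other split, 1032, was the one that set 0 and 15 min against 45 and 60 min and so follows the time after TNF. With the time block the real split called 2446 and the highest other 0, and 1 of the 8 splits gave as many, which is too few splits for a share under 0.05. Embryo sex cannot be told apart from genotype. On X or Y lay 3.03% of the calls and 3.004% of the tested genes, and the tested genes there could hold at most 18.5% of the calls, so this share says nothing about effects of sex on other chromosomes. Of autosomal genes within 10 Mb of Rela or Rel 11.3% were called, against 16.4% elsewhere (odds ratio 0.648, 95% interval 0.441 to 0.926, Fisher p = 0.0158). Calls were thus not more frequent near the targeted alleles. The window held 311 tested genes, 35 of them called, so it could not hold most of the 2446 calls whatever the odds ratio. This value therefore does not decide on segments carried along with the alleles, and effects of such segments on genes elsewhere were not tested. The share of calls higher in KO, 41.9% or 14.1% with total counts, depends on the scaling and so does not decide on leukocytes in WT alone. Among genes called at least 2-fold apart under both scalings, 147 were higher and 650 lower in KO. The 18.4% that were higher argue against such leukocytes for that part, and for the genes lower in KO they cannot be told apart from an effect of genotype. Different embryos or cell make-up between the 2 genotypes stays open.

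Cartilage genes were far higher in the KO 0 min library than in the other 7, at a summed 448 CPM against at most 70.8. The median log2 ratio of 6 cartilage markers was -3.93 at 15 min, against -0.06 for 25 fibroblast matrix genes, and stood at -4.27 and -2.64 at 45 and 60 min. With 1 library at 0 min, a share of cartilage cells in that library cannot be told apart from a fall after TNF. No biological explanation was tested.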

How the results depend on the processing

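The alternatives with a 15 min baseline and without the 3 ribosomal gene models were chosen after the data were seen. Counts are given as higher and lower. RLE scaling, robust empirical Bayes, a filter of 50 counts and leaving out the ribosomal gene models moved no count of the 4 tested results by over 1.5 times. Low counts and single libraries per time limit the depth of every result. Unless construction shows it, the cause was not tested. For named genes in the late WT response, 635 combinations of gene and alternative kept direction and side of the threshold. With the direction kept, 23 lost the call and 3 gained it, and 1 reversed direction. For KO 284 were kept, 29 lost and 6 reversed, for the difference 355, 32 and 9, and for genotype 435, 24 and 0. Some of the reversed ones lost a call too, and these are not among the lost.

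Total counts gave 304 and 280 for WT, 57 and 156 for KO, 96 and 2 for the difference and 477 and 2902 for genotype, and shifted the median log2 fold change of all genes by -0.21 in WT, -0.20 in KO and -0.18 for genotype. No filter gave 248 and 30, 8 and 9 and 14 and 0 for the first 3, and DESeq2 gave 379 and 47, 139 and 16, 62 and 0 and 574 and 961 for all 4. A baseline of 0 and 15 min gave 1097 and 572, 706 and 438 and 179 and 19, and a straight line over time 964 and 431, 526 and 269 and 85 and 2. With limma-voom, 0 genes had a larger KO response. A 2-fold minimum left 125 lower in WT and 222 and 650 for genotype, and no time block 359 and 708. The 15 min baseline gave 130 lower in WT and 72 higher in KO. Leaving out 1 library gave 551 to 738 higher and 180 to 276 lower for WT, 136 to 459 and 33 to 317 for KO, 51 to 153 and 0 to 12 for the difference, and 410 to 975 and 734 to 1450 for genotype. An estimated correlation left 0 lists called in each of the 4 results.

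At 15, 45 and 60 min, total counts gave 46, 397, 563 in WT and 33, 135, 424 in KO higher, and 691, 916, 760 in WT and 499, 1291, 508 in KO lower. A 4-fold minimum gave 21, 149, 164 in WT and 6, 26, 31 in KO higher, and 2, 26, 37 in WT and 24, 39, 41 in KO lower, by construction fewer. A minimum of 100 counts gave 46, 370, 448 in WT and 33, 174, 204 in KO higher, and 10, 96, 132 in WT and 21, 94, 129 in KO lower, also by construction.

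With the KO baseline from 15 min the cartilage genes changed sign in KO, to 0.73 for Col9a1, 1.26 for Col2a1 and 1.77 for Acan. Junb in WT changed sign to -0.20 with the WT baseline from 15 min. Values that were not called also changed sign. Nfkbia in KO was -0.0772 with total counts. Leaving out 1 library, its lowest value was -0.0700 without KO 45 min and its highest 0.34 without KO 60 min, and for Tnfaip3 these were -0.20 and 0.69. The difference in response was 0.40 for Fos and 0.38 for Egr1 with 0 and 15 min as baseline, 0.67 and 0.57 with a straight line, 1.80 and 1.28 with the KO baseline from 15 min, and 0.31 and 0.53 without the KO 45 min library. Without the KO 60 min library they were -0.73 and -0.57. Egr1 was 0.14 without the WT 60 min library. No paired analysis was possible by replicate number because each group holds 1 library. The genotype comparison pairs the libraries by time, and without that block its counts were 359 and 708.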

Other observations

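The test of how KO responses compare with WT was chosen after the responses had been seen. Members of other cell type and process lists also differed between the genotypes. Of 25 fibroblast matrix genes 2 were higher and 8 lower in KO, with Postn at -0.91 ± 0.09 and Pdgfra at -0.68 ± 0.07. The calls of Postn and Pdgfra were lost in 1 of 20 and 2 of 20 alternatives, both under a 2-fold minimum and Pdgfra also without the time block. Of 11 smooth muscle and myofibroblast genes 4 were higher (7 adjusted over the list alone), Actg2 among them (1.80 ± 0.22). Of 4 adipocyte genes 2 were lower, Lpl (-2.51 ± 0.24) and Cd36 (-4.19 ± 0.49). Of 18 stress response genes 4 were higher and 2 lower, of 26 cell cycle genes 3 were lower, of 20 p53 targets 1 was lower, and of 11 chromatin retained RNAs 3 were higher and 2 lower. Among 5 endothelial markers 2 were higher and 1 lower, among 3 epithelial markers 2 were higher, and among 4 neural and glial markers 1 was higher and 1 lower. No call was made among 4 muscle markers or 9 mitochondrial transcripts (edgeR). In the late WT response 2 p53 targets and 2 matrix genes rose, with Tnc at 1.21 ± 0.19, and 1 gene each of the stress, smooth muscle and endothelial lists.

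The time a polymerase needs to cross a gene may set how early its exons gain reads. Over the 68 genes that rose in WT and responded more than in KO, the share of the late log2 response reached at 15 min was set against genomic span. Spearman's rho was -0.58 and Pearson's r with log10 span -0.56, each with a permutation p of 1e-05, also 1e-05 adjusted over the 2 relations, which is the smallest that 100000 permutations can give. Without the 2 genes farthest from the median span r was -0.56. The 13 genes that had reached at least 0.5 of the late response had a median span of 5.3 kb, and the others 24.5 kb. Some genes, named after their values were seen, departed from this in either direction. Nfkbie (7.45 kb) and Icam1 (12.8 kb) had shares of 0.20 and 0.17, and Nfkbiz (27.5 kb) had 1.17. This is a relation across genes, which are not independent replicates, within 1 library per time. It cannot separate the time to cross a gene from other traits that go with span, which were not tested.

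Genes that rose late in KO may not need RelA and cRel. Over the 198 genes called higher in KO the median ratio of the WT to the KO log2 response was 0.767, with quartiles of 0.534 and 1.14. The genes were chosen for their KO response, which favours ratios under 1.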
